A study of Zea mays subsp. mays with 4 samples.

How the data were processed

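RNA was measured in shoots and roots of seedlings of the maize inbred line Mo17, grown for 2 weeks at 25 degrees under 16 h of light and 8 h of dark, per the labels. The labels name 4 libraries, 2 of shoot and 2 of root, numbered 1 and 2 within each tissue. Nothing in the labels says whether the 2 libraries of a tissue came from separate plants, so p-values measure only the spread between these samples, which may be technical. CASAVA 1.4, TopHat and Cufflinks are named in the submitters' processing notes, without their roles. The aligner settings, the transcript set behind the tables and its genome build are not given in the sources used here.

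The deposited tables hold 1 value per tissue for each of 122914 loci and each of 190236 isoforms, with a modelled variance and a status, in the layout of Cuffdiff count tracking. The values are treated here as a signal, namely a scaled count, because the deposited values are neither raw counts nor values of single libraries. Their low values had the form of a mean over 2 libraries after division by size factors: in root the smallest recurring values were 0.368 and 0.399, and in shoot 0.582 and 0.599, and most other low values were sums of whole multiples of these steps. The variance columns were deposited by the authors, and their square root is called the modelled SD below. The part of the variance listed for the uncertainty of read assignment was 0 throughout, so the modelled SD may leave that error out. Whether the total variance holds it in another form is not given in the sources used here. How the authors' software modelled the rest is not given either. There were 0 columns of other samples.

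A deposited annotation of AGPv3, the third assembly of the maize B73 genome, lists 109945 loci, 136933 transcripts and 109886 gene names. Its locus and transcript identifiers look like those of the tables but are numbered differently. Under its own map, the isoforms of a locus added up to the locus value in both tissues, within 1%, for only 15 of 48719 loci with a value above 0. In the tables themselves, a run of consecutive isoforms added up to the locus value in both tissues, within 0.002%, for 54388 of 54427 loci. The tables hold 12969 loci and 53525 isoforms whose identifiers are absent from the annotation. Gene names, coordinates and chromosomes were therefore not carried over, and loci are reported without names. The 33 gene lists fixed before the data were examined, and the planned shares of the plastid and mitochondrial genomes, need those names and were not used here.

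The planned edgeR test needs counts per library, so it was not run. As planned for tables that hold the mean of a tissue, values were set side by side without a test. A locus was compared if its status was OK in both tissues and its value was at least 10 in 1 of them. Ratios are on the scale log2(value + 1), which understates the change of low loci. A locus was counted as higher in a tissue if it was at least 2-fold different on that scale and if the difference exceeded 2 SDs, with the SD from the sum of both modelled variances. For comparison, 20 simulations drew 2 libraries per tissue around the mean of both tissues with no difference, taking the deposited dispersion variance, as a smooth function of the value, for the variance of 1 library. The minimum of 10, the condition on the modelled SD, the range of recovered reads and the isoform thresholds were set after the layout and values of the tables were seen. In a run on simulated data with 36094 loci, this count found 92% of 100 loci changed 4-fold and 36% of 100 loci changed 2-fold.

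Whole reads of single libraries were recovered where a value under 30 was a sum of whole multiples of both steps in exactly 1 way, within the rounding to 6 significant digits. This held for 13466 of 23171 root values (58.1%) and 12964 of 22120 shoot values (58.6%). As a control, slightly altered steps gave whole reads for 0.360% of root values and 0.267% of shoot values. On simulated values every whole-read locus was recovered, and 0.308% of the recovered root values and 0.155% of the recovered shoot values were wrong. Because 58% is far from nearly all loci, no count model was used. The recovered libraries are called a and b, since the values do not tell which is replicate 1. They were compared by limma 3.58.1 in R 4.3.3, with a mean-variance trend on log2(scaled count + 1), Benjamini-Hochberg adjustment and a threshold of 0.05. In simulated data for these 3486 loci, limma found 58% of 100 loci changed 4-fold and 86% of 100 loci changed 8-fold, and called 11 unchanged loci. These simulated loci were not selected by a high value in 1 tissue, so the 11 leave out the effect of that selection. They were drawn with a single fixed overdispersion, while the spread of the recovered libraries varied with tissue and value. Where the real spread was wider, the shares found may be too high and the 11 too low.

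Since the tables hold no map from isoforms to loci, each isoform was assigned to a locus through the runs of consecutive isoforms described above, and the isoform shares rest on this inferred assignment. Shares were computed in loci with at least 2 isoforms above 0, a value of at least 50 in both tissues and status OK for each isoform. Shares were called shifted if they moved by at least 20 percentage points and by over 2 modelled SDs, where the SD treats the locus total as fixed. The tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The rule for named genes asked for a gene name, which no locus has. The 4 loci given by identifier were chosen after their values were seen, as the 2 most abundant among those counted as higher in each tissue.

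The tables hold no depth per library. From the steps, the summed values, which leave out failed and skipped loci, correspond to between 44208582 and 47947943 reads or read pairs in both root libraries together, and to between 39203697 and 40337538 in both shoot libraries. A count of 0 allows up to 3 reads over both libraries of a tissue, or 1.20 scaled counts in root and 1.80 in shoot. This limit covers counting error only. Alternatives were other scalings, pseudocounts, minimum values and numbers of SDs, limma-voom, a minimum on the mean of all libraries, and leaving out each recovered library.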

Results

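RNA abundance was compared between shoots and roots of 2-week-old seedlings of Mo17, an inbred maize line widely used as a parent of hybrids. There were 2 libraries per tissue, and each deposited value was the authors' scaled count for a whole tissue. The comparison addresses which transcribed loci differ between the aerial and the underground part of the seedling. The summed scaled counts were 17636832 in root and 23491018 in shoot. Of 122905 loci with a valid estimate in both tissues, 44715 had a value above 0 in both, 4446 in shoot only and 5258 in root only, and 68486 were listed at 0 in both. A value of at least 10 was reached by 33766 loci in shoot and 33325 in root.

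Shoots and roots differed at many loci in both directions. Of 37532 loci with a value of at least 10 in 1 tissue, 5913 were higher in shoot and 5577 were higher in root by at least 2-fold and over 2 modelled SDs, together 30.6% of the loci compared. The median log2 ratio of shoot to root was 2.81 among the loci higher in shoot and -2.60 among those higher in root. These medians depend on the pseudocount, since 376 of the loci higher in shoot were listed at 0 in root and 538 of those higher in root at 0 in shoot. With the lower tissue raised to what a count of 0 allows, the median fold was 2.95 in shoot and 2.66 in root on the log2 scale. On that basis 2516 loci were at least 10-fold and 582 at least 100-fold higher in shoot, and 2019 and 317 in root. Over all compared loci, the log2 values of both tissues had a Pearson correlation of 0.65 across loci, which are not independent replicates.

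Without the condition on the modelled SD, 8519 loci were at least 2-fold higher in shoot and 7764 in root, and 21249 loci (56.6%) lay within 2-fold. In 20 simulations of unchanged loci, a mean of 325.9 loci were at least 2-fold higher in shoot and 333.3 in root, and a mean of 15.7 loci met both conditions in the direction of shoot and 19.2 in that of root, with a highest count of 22 and 27. These simulations used the deposited dispersion variance, which was below the spread between recovered libraries at most low values. With that observed spread the means were 1035 and 1051 for the fold alone and 180.1 and 187.8 for both conditions, with highest counts of 197 and 214 for both. That spread was measured only under 100 scaled counts, at loci with whole reads. Loci above 100 took the ratio of the range from 30 to 100, so their part of these means is an extrapolation. The table has no values for single libraries, so these counts have no replicate test and no p-value. The split between the directions is largely set by the scaling: the deposited values had a median log2 ratio of -0.01, and with equal totals 4606 loci were higher in shoot and 7807 in root, which moves the share higher in shoot from 51.5% to 37.1%.

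**Figure D1:**
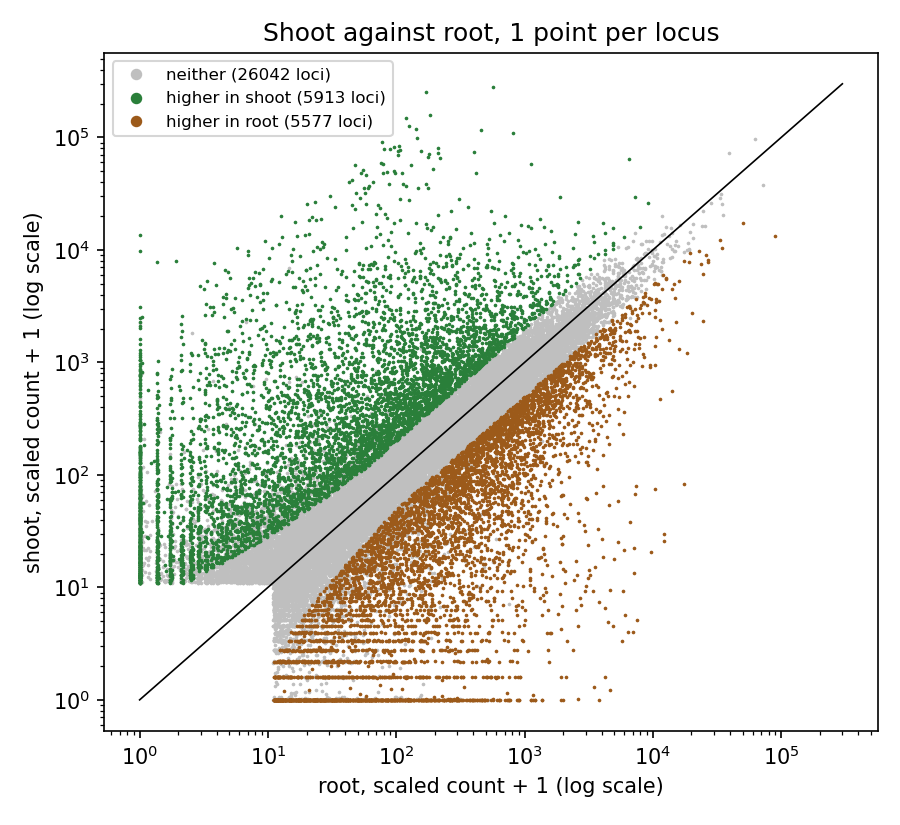
Scaled count + 1 of each locus in root (x axis, log scale) and shoot (y axis, log scale), for the 37532 loci with a value of at least 10 in 1 tissue; the line marks equal values. Green points are the 5913 loci higher in shoot and brown points the 5577 higher in root by at least 2-fold and over 2 modelled SDs, and points along the left and lower edges are loci listed at or near 0 in 1 tissue.

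The shoot transcriptome was concentrated in fewer loci than the root transcriptome. The 10 most abundant loci held 6.42% of the scaled counts in shoot and 2.76% in root, and the 100 most abundant held 21.8% and 10.5%. The smallest number of loci that held 50% of the scaled counts was 1306 in shoot and 2378 in root. A value of at least 10000 was reached by 213 loci in shoot and 103 in root. Of the 100 most abundant shoot loci, 89 were higher in shoot, 85 of them at least 10-fold on the log2(value + 1) scale, and 1 was higher in root. Of the 100 most abundant root loci, 46 were higher in root, 10 of them at least 10-fold. The lists shared 11 loci. These ranks and shares leave out 2 loci whose shoot estimate was skipped for too many reads and whose abundance in shoot is unknown.

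**Figure D2:**
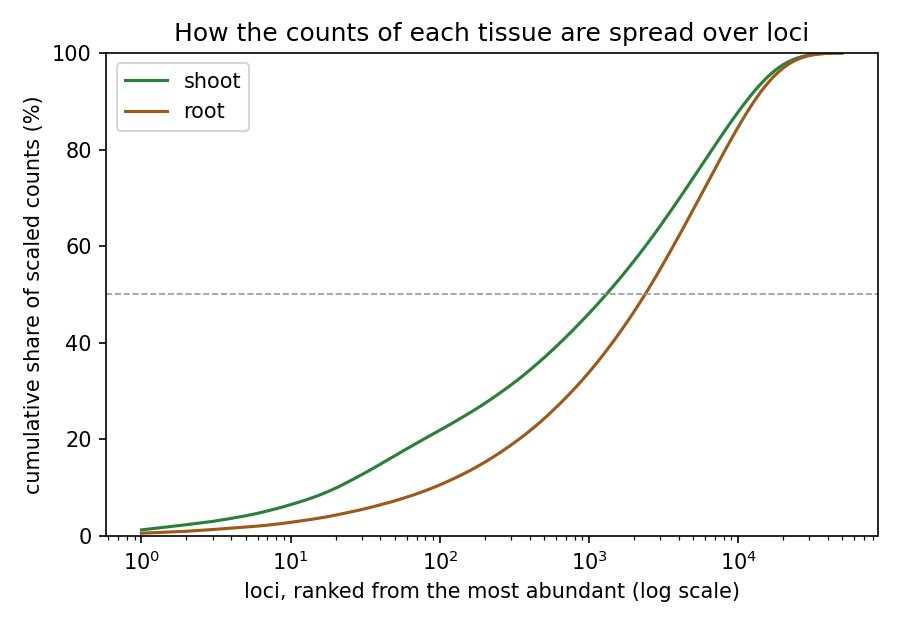
Cumulative share of the scaled counts of shoot (green) and root (brown), in percent, against the number of loci ranked from the most abundant (log scale); the dashed line marks 50%. The shoot curve crosses it at 1306 loci and the root curve at 2378 loci.

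Among loci with a valid estimate, the most abundant in shoot, XLOC_100348, had a scaled count of 280164 with a modelled SD of 20162 in shoot, and of 569 with a modelled SD of 93.7 in root, a ratio of 493. The next among the loci higher in shoot, XLOC_114341, had 254092 with a modelled SD of 24042 in shoot and 168 with a modelled SD of 40.9 in root, a ratio of 1509. Its root value, 0.0663% of its shoot value, was the lowest share among the 87 loci of at least 20000 in shoot. In root, the most abundant locus was XLOC_019185, with 89303 and a modelled SD of 11989 in root against 13230 and 2017 in shoot, a ratio of root to shoot of 6.75. XLOC_054598 followed among the loci higher in root, with 50575 and a modelled SD of 9439 in root against 17540 and 2915 in shoot, a ratio of 2.88. The deposited files used here do not pair these identifiers with gene names.

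With the authors' scaling, the share of loci higher in shoot was largest in the most abundant class. Of 143 loci with a mean of both tissues of at least 10000, 82 (57.3%) were higher in shoot and 16 (11.2%) in root. Between 1000 and 10000 the counts were 964 and 658 of 4592 loci. Between 100 and 1000 they were 2662 and 2548 of 16166 loci, and between 10 and 100 they were 1847 and 2049 of 14227 loci. The median modelled SD fell from 38.3% of the mean in the lowest class to 15.9% between 1000 and 10000 and was 19.2% in the highest class, so that small differences were harder to detect at low values.

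**Figure D3:**
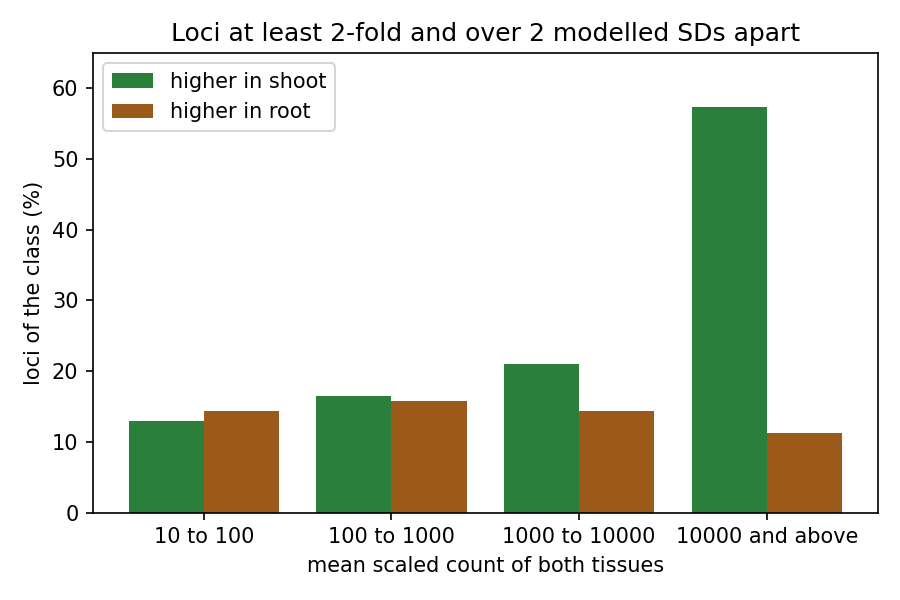
Share of loci, in percent of each class, that were higher in shoot (green bars) or in root (brown bars) by at least 2-fold and over 2 modelled SDs, by the mean scaled count of both tissues. In the class of 10000 and above the shares are 57.3% and 11.2%, and in the class of 10 to 100 they are 13.0% and 14.4%.

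Many loci were listed at 0 in 1 tissue. A value of at least 10 in shoot with a root value of 0 was found at 553 loci, and the reverse at 720 loci. Set against the limit that a count of 0 allows, the observed values were at least 8.36-fold higher in shoot or at least 5.56-fold higher in root. The error of the higher value is not in these folds, so they are no lower limits of the true fold. At values of at least 100 there were 78 such loci in shoot and 135 in root, and at values of at least 1000 there were 12 and 6. The highest shoot value with a root value of 0 was 13711, and the highest root value with a shoot value of 0 was 3827. An exact 0 in an estimated value can also arise from the assignment of reads to another locus.

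At low abundance, where whole reads could be recovered for each library, loci were also called different between the tissues against the spread between libraries. Of 3486 loci under 30 in both tissues and at least 10 in 1 of them, limma called 328 higher in shoot and 303 higher in root at an adjusted p of 0.05 (18.1%). The median log2 fold change was 3.62 for the calls in shoot and -3.70 for the calls in root, with a median SE of 0.60 among the calls. Of these calls, 149 of those higher in shoot were listed at 0 in root and 176 of those higher in root at 0 in shoot. A tissue at 0 in both libraries shows no spread. At these calls the spread came only from the libraries of the other tissue and from the trend over all loci. With the lower tissue raised to what a count of 0 allows, the median fold was 3.68 in shoot and 3.16 in root on the log2 scale. The other tissue lay at or under that limit in 273 of the 328 calls in shoot and 278 of the 303 in root. These medians therefore rest mostly on observed values set against that limit, with the error of the higher value left out. Loci enter this set by a high value in 1 tissue, which favours differences. With the minimum of 10 set on the mean of all 4 libraries instead, which leaves out loci under about 20 in 1 tissue and at 0 in the other, limma called 103 loci in shoot and 103 in root among 2246. Without a filter on low values, limma with a trend gave 0 calls in both directions among 14194 loci, and limma-voom gave 419 in shoot and 312 in root.

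The libraries of a tissue resembled each other more than those of different tissues at these loci. The Pearson correlation across loci was 0.66 between the root libraries and 0.66 between the shoot libraries, and between -0.29 and -0.12 across tissues. The set was chosen to be low in both tissues and at least 10 in 1, which lowers correlations across tissues and can raise those within a tissue. What unchanged loci would give under this selection was not simulated, so the contrast is no test of a tissue difference. The median absolute log2 difference between the libraries of a tissue was 0.68 in root and 0.60 in shoot. limma-voom on the same reads called 320 loci higher in shoot and 335 in root, of which 300 and 292 were also called by the trend fit. The calls of the trend fit depended on each single library: leaving out root library a or b left 0 calls in shoot, with 196 and 206 in root, and leaving out shoot library a or b left 0 calls in root, with 168 and 163 in shoot. At an unadjusted p under 0.05, limma counted 913 and 812 loci without root library a or b and 774 and 743 without shoot library a or b, and limma-voom 549, 506, 829 and 794. limma-voom called 0 loci in both directions without root library a or b. Without shoot library a or b it called 178 and 249 loci in shoot and 327 in root in both cases, close to the 335 with all libraries.

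**Figure D4:**
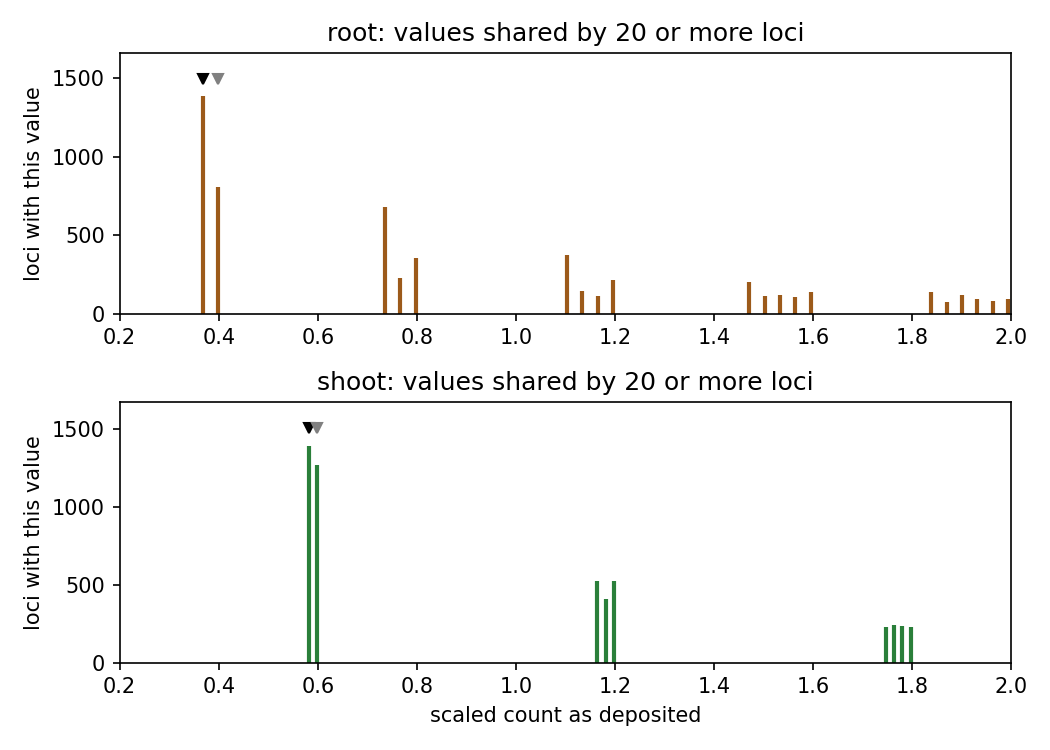
Number of loci (y axis) that share each exact low scaled count (x axis) in root (upper panel) and shoot (lower panel), for values held by at least 20 loci. Triangles mark the steps of 1 read in library a (black) and b (grey), at 0.368 and 0.399 in root and 0.582 and 0.599 in shoot, and whole reads account for 65.2% of the root values and 62.9% of the shoot values under 1.

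At most loci no isoform share shifted beyond the thresholds. This does not show equal usage, since the modelled SD of a shift was large. Among 11350 loci with at least 2 isoforms above 0 and a value of at least 50 in both tissues, the leading isoform made up a median of 79.3% of the locus in root and 78.5% in shoot. The largest shift of an isoform between the tissues had a median of 7.73 percentage points, against a median modelled SD of 14.8 points for a shift. The leading isoform differed between the tissues at 1563 loci (13.8%), a count for which no chance level was simulated. An isoform shifted by at least 20 points and over 2 modelled SDs at 562 loci (4.95%), and 371 loci met both conditions. Isoforms were assigned to loci by inference, from consecutive isoforms that added up to the locus value. These shares are estimates of the authors' software without values for single libraries, and no test was made.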

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

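The tests of both patterns weighed in this part were chosen after the results were seen.

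Signals outside the main comparison came from entries with a failed or skipped estimate. At 8 loci the estimate had failed or was skipped in 1 tissue while the other tissue held a value above the limit that a count of 0 allows. Of these, 2 loci were marked HIDATA in shoot, which Cuffdiff uses for loci with too many reads to process, and their root values were 709 and 72.2. The failed loci included shoot values of 6054 and 1073. Among the isoforms marked LOWDATA, 1839 had a root value above 0 and 1852 had a shoot value above 0. These isoforms were left out of the isoform comparison, together with all other isoforms of their loci.

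The first pattern weighed is the shoot total, which was 1.33 times the root total although the median log2 ratio was -0.01. Deeper sequencing of shoot was weighed through read totals. By the recovered steps, at most 40337538 reads lay behind the summed shoot values and at least 44208582 behind the summed root values. This comparison cannot decide, since the values had the form of counts divided by size factors. Such division takes a uniform difference in depth out of the ratio of totals, whichever tissue had more reads. Reads of the skipped loci are in neither sum, so the full depth of the libraries is unknown. Without the 1000 most abundant loci, ranked by the mean of both tissues, the ratio of totals fell to 1.04, and without the 100 most abundant it was 1.13. A candidate explanation is that abundant loci of the shoot carry the excess, with the median ratio of the compared loci near equal. The loci were ranked on the same values that were summed, which favours such a fall. The fall is therefore no independent test of this explanation. A difference between the tissues in total RNA stays open and was not tested.

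The second pattern is a lower edge in root: of 87 loci of at least 20000 in shoot, none had a root value under 0.05% of the shoot value, and 37 lay between 0.05% and 0.2%. Shoot reads carried into the root libraries, by a misread barcode or by tissue or RNA carry-over, may give such an edge. Among 592 loci of at least 5000 in shoot, 3 lay under 0.05% beyond counting error (Poisson p under 0.001), where chance allows at most 0.592, and 1 of the 3 was listed at 0 in root. None of these 3 was among the 87 loci that show the edge, and they are too few to decide, so carry-over stays open. Low transcription in root of the same loci stays open: the 25th percentile of the ratio was 1.60 times the 5th, and the design has no library that could separate these sources.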

How the results depend on the processing

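Chosen after seeing the data were the scaling to equal totals, the pseudocounts, the minimum of 50 and 3 modelled SDs. So were the wider range of recovered reads, the minimum on the mean of all libraries and the simulation with the observed spread. The isoform settings other than the isoform minimum of 10 were also chosen then. The other alternatives were fixed in kind before the data were examined. Many of them were applied to the recovered reads or to the condition on the modelled SD, which were set afterwards. Of 58 counts under alternatives, 39 stayed within 1.5 times the count reported. Among the pooled counts, a minimum of 50 gave 5581 loci at least 2-fold higher in shoot, and 3 modelled SDs gave 3916 loci higher in shoot. Equal totals shift the median log2 ratio by -0.41 and the upper quartile by -0.10; with the upper quartile, 5533 loci were higher in shoot and 5979 in root. With the recovered reads, no filter on low values gave 0 calls in both directions by limma with a trend, with 2361 of 14194 loci at an unadjusted p under 0.05, while limma-voom gave 419 in shoot and 312 in root; the cause was not tested. Values up to 100 gave 876 calls in shoot and 910 in root by the trend fit among 6496 loci. Leaving out 1 library gave between 0 and 168 calls in shoot and between 0 and 206 in root by the trend fit, and between 0 and 249 in shoot and between 0 and 327 in root by limma-voom; a tissue left with 1 library is assumed to vary like the other. With the minimum of 10 on the mean of all libraries, the trend fit gave 103 calls in shoot and 103 in root among 2246 loci, and limma-voom 128 and 146. A locus minimum of 200 gave 768 loci with a different leading isoform and 300 with a shifted isoform; 3 modelled SDs gave 200 and a shift of 40 points gave 339 shifted loci. No paired analysis was possible because the values are means of a tissue and the recovered libraries carry no replicate number. Not run for lack of counts per library, gene names or chromosomes were DESeq2, the isoform tests, leaving out libraries from the tissue values and isoforms, the gene lists by camera and fry, and the settings and shares for organelle genes; limma-voom was planned on unrounded values and run on the recovered reads. Depth limits the low loci most, since a value of 0 allows up to 3 reads.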

Other observations

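All tests in this part were chosen after the results were seen.

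Loci with consecutive identifiers leaned to the same tissue. Over 15059 such pairs with both loci compared, the log2 ratios of shoot to root had a Pearson correlation of 0.14 across pairs (bootstrap interval 0.12 to 0.16), and the highest of 1000 shuffled orders gave 0.03. It was 0.08 at an identifier distance of 2, 0.03 at 5 and 0.01 at 10. Reads divided in fractions between overlapping loci are argued against for 771 pairs of loci under 100 whose values were whole reads or no reads. Over these pairs the correlation was 0.35 (0.27 to 0.43), and over 1042 pairs under 100 without whole reads it was 0.24 (0.17 to 0.31). Reads assigned in full to a single locus, or counted in full at both, also give such values, so these forms of assignment stay open. The intervals resample pairs as independent, although consecutive pairs can share a locus. A gene entered as several loci could also give the pattern, as could neighbouring genes used in the same tissue; the decline to 0.0280 at a distance of 5 does not separate them, since the tables hold no coordinates.

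Values that were not sums of whole reads recurred at the same loci in both tissues. Of 14900 loci above 0 and under 30 in both, 5719 were not whole in both and 7895 were whole in both, with an odds ratio of 109.4. Among loci with 1 isoform above 0, 38.3% of root values and 38.3% of shoot values were not whole, against 59.3% and 57.1% in loci with more isoforms. A value above 0 but below the worth of 1 read was listed at 1163 loci in root and 1183 in shoot. A value of 0 in the other tissue was about as frequent for whole as for other values between 10 and 30, at 5.81% and 5.72% of root loci and 4.55% and 5.11% of shoot loci.

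The spread between the recovered libraries was set against the deposited dispersion variance, taken as that of 1 library. Between 1 and 3 scaled counts the variance estimated from the median was 2.82 times the modelled one in root and 3.04 times in shoot, and between 3 and 10 it was 2.50 and 2.70 times. The estimate assumes normally distributed values, which a few reads per library do not give. Between 1 and 3, whole reads can give only a few values of the difference, and the median fell on 1 of them. The ratios at the lowest values are therefore rough. Between 10 and 30 scaled counts, the variance estimated from the median was 1.81 times the modelled one in root and 1.39 times in shoot. Between 30 and 100 it was 1.31 times in root and 0.967 times in shoot. The share of wrongly recovered values was estimated from altered steps at 4.46% in root and 2.51% in shoot in the upper range.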
